A study of Mus musculus with 359 samples.

How the data were processed

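RNA sequencing was used to measure gene expression in liver and lung of male and female B6C3F1 mice given 4-methylimidazole (4-MEI), a nitrogen heterocycle formed when sugars are heated with ammonia. Per the labels' protocols, libraries were made with the TruSeq Stranded mRNA kit. Per the submitters' processing notes, the authors used Trimmomatic, Bowtie2, SAMtools and HTSeq with the mouse build mm10, and the versions, the annotation and the strand setting of the counting are not given in the sources used here. The deposited values are raw read counts per gene, 1 column per library, with no normalization, in 6 tables of 24421 gene symbols, 1 for each tissue and day. All values were whole numbers with a different total in each column. The lung table of day 28 held 1 further column without a name, which equalled the sum of the 60 libraries in all 24421 rows and was not used.

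Groups were taken from the sample titles: 359 libraries in 60 groups, 59 groups of 6 and 1 group of 5. At day 28 the titles and the characteristics named another dose in 96 libraries, and another sex in 48 of these. Xist, which is expressed from the inactive X chromosome, and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty were used to check the sex. A sum of the Y-linked genes above 5 CPM (counts scaled to the library total) was read as male, and Xist above 50 CPM as female. The Y-linked genes matched the title in 359 of 359 libraries and the characteristics in 311. Xist matched the title in 358. The exception was replicate 78 (female, 300 mg/kg-d, lung, day 2), with 0.639 CPM of Xist and 0.0639 CPM of Y-linked genes, and it was kept. No table held identical libraries.

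Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, scaled with TMM, and fitted with quasi-likelihood models with robust spread, with 1 mean for each of the 10 groups of a table. Counts given without a setting are from these fits. Each dose was compared with the vehicle group of the same tissue, day and sex. P-values were adjusted by Benjamini and Hochberg within a contrast, with a threshold of 0.05. Standard errors (SE) were the fold change divided by the square root of the test statistic. Differences of the highest dose effect between sexes were tested in the same fits, and differences between liver and lung, or between day 28 and day 5, in fits of the joined groups. Between 12627 and 12904 genes were tested in liver and between 15240 and 15675 in lung. CPM values given with a standard deviation (SD) are TMM-scaled.

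A set of 19 pathway lists and 22 cell type marker lists was fixed before the data were examined, together with the tests, the alternatives and the rule for naming genes. Lists of a tissue were tested at the highest dose with camera of limma 3.58.1, two-sided, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a contrast. By the rule, the genes named are, for each tissue and day, up to 6 with the highest and 6 with the lowest mean fold change among genes past the threshold in both sexes at the highest dose, up to 3 further genes in each direction in each sex, up to 4 members past the threshold of each list described, the 4 genes with the smallest adjusted p of each difference test, and all genes of contrasts with 5 or fewer calls. The lists described were chosen after their values were seen. Low-expressed genes and predicted gene models were passed over in the first groups.

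The alternatives were RLE size factors, no low-count filter, DESeq2 1.42.0, only the groups compared, the number in the title as a block between tissues, camera with estimated correlations, the fry test and a prior count of 0.5. Models with the place of the title's number in its block of 8 numbers, or with a trend on transcript length removed (GENCODE release M21), and fits without replicate 64, 66, 78 or 176 were added after seeing the data. For each count, 30 splits of the same libraries into groups of the same sizes, the real one included, were fitted. Coordinates are from GRCm38.p6, the build mm10.

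The scripts that test genes and lists were tested on simulated data. For the highest dose against vehicle in liver of males at day 2, simulated over 12546 genes, the test recovered 67.2% of genes changed 1.5-fold, 94.0% of those changed 2-fold and 98.5% of those changed 4-fold, and 6.49% of 185 calls were unchanged genes. These data held no length trend, place effect or outlying library, and low-expressed genes were not among those changed. With a length trend added to the highest dose group, 95.6% of 4030 calls were unchanged genes, and 5.98% of calls after its removal. Library totals ran from 7253910 to 22527309 counts.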

Results

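Livers and lungs were collected after 2, 5 or 28 days of 4-MEI. Mice were dosed by gavage for 2 days with 0, 50, 100, 200 or 300 mg/kg-d, or fed 0, 150, 300, 1250 or 2500 ppm for 5 or 28 days. Each tissue, day, sex and dose held 6 libraries, except the females fed 2500 ppm for 5 days, with 5 lung libraries. Library totals were 8457034 to 20405658 counts in liver at day 2, 11070867 to 22527309 at day 5 and 10239848 to 18084863 at day 28. Lung totals were 7253910 to 20232366, 8081043 to 21473135 and 11692340 to 18207432 counts. The series asks which genes of the target organs respond over dose and time. Cyp2c, Cyp3a, Cyp2b and Saa genes have near-identical copies among which reads could be split, so their values are uncertain at the level of the single gene.

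**Figure D1:**
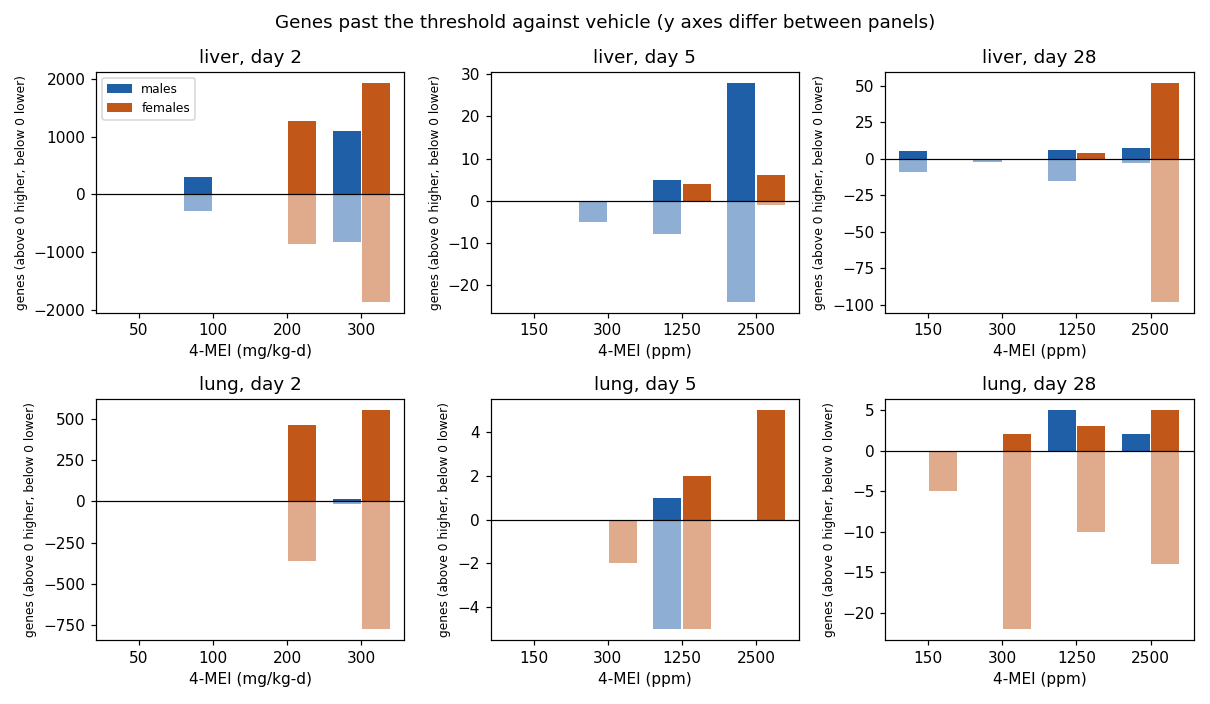
Genes past the threshold (y axis, number of genes; above 0 higher, below 0 lower) at each dose (x axis) against vehicle, in males (blue) and females (orange), in 6 panels with separate y axes. The count in liver at day 2 with 300 mg/kg-d was 1908 in males and 3787 in females.

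In liver after 2 days of gavage, the acute phase genes Saa1, Saa2, Lcn2 and Hp rose and the lipid synthesis genes Thrsp, Acly and Acss2 fell in both sexes at 300 mg/kg-d. Saa1 and Saa2 encode serum amyloid A, which the liver secretes in inflammation, and Lcn2 encodes the iron-binding lipocalin 2. Thrsp and Acly drive the making of fatty acids from sugar. Cyp2b10, the classic target of the nuclear receptor CAR, also rose.

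Saa1 (chromosome 7, 46740497 to 46743181) rose from 18.8 CPM (SD 10.1, n = 6) to 497 (SD 245, n = 6) in females, by 4.72 log2 (SE 0.63, adjusted p 5.14e-07). In males it rose by 3.94 (SE 0.61, adjusted p 3.84e-05), with 1 library, replicate 67, at 1903 CPM and the next at 458. Saa2 rose by 5.15 in males, where 4 of 6 libraries lay above the vehicle mean, and by 4.62 in females. Lcn2 rose by 1.81 and 2.57 and Hp, the haemoglobin-binding haptoglobin, by 0.57 and 0.93 in males and females. In males replicate 67 also held 1172 CPM of Saa2 and 38.96 of Lcn2, where the next library held 9.04 of Lcn2. Cxcl1, a neutrophil attractant, rose by 2.24 in females. Cyp2b10 (chromosome 7, 25897658 to 25926624) rose by 1.94 (SE 0.54, adjusted p 0.011) in males and by 2.48 (SE 0.54, adjusted p 0.000462) in females, in 6 of 6 libraries each. The cell cycle regulator E2f8 rose by 1.60 and 1.34, and the trehalase gene Treh by 1.12 and 2.18.

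Thrsp fell by 1.74 in males and by 1.90 in females, Acly by 1.12 and 1.73, and Acss2, which makes acetyl-CoA from acetate, by 1.06 and 1.40. Mlxipl, which encodes the glucose-sensing factor ChREBP, fell by 0.40 and 0.59. Chrna4, a nicotinic receptor subunit, fell by 4.28 and 5.11, Fam65b by 1.67 and 2.14, Mmd2 by 1.11 and 1.46 and the long noncoding RNA Neat1 by 0.94 and 1.63. In females Pnpla3, a lipid droplet lipase, fell by 3.63 and the repressor Bcl6 by 1.92. The sterol synthesis genes Mvk, Pmvk and Sc5d fell by 1.34, 1.48 and 1.32 in females, as did Lss (adjusted p 0.00165). Metallothionein Mt2, Fam107a and the p53 target Cdkn1a rose by 3.19, 4.08 and 2.94 in females, Cdkn1a in 4 of 6 libraries. In males Acot3, Rab30 and Socs2 rose by 2.18, 1.53 and 1.89. The PPAR-alpha target Acot1 rose by 1.37 in males and 1.38 in females, and Pex11a, Acadm and Cyp4a31 rose in females by 1.11, 0.44 and 1.42. The interferon-stimulated genes Dhx58, Isg15 and Oasl1 fell by 0.82, 0.77 and 0.99 in males and by 0.90, 1.28 and 1.15 in females, and Xaf1 fell by 0.97 in females.

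Xist and the female-biased Cyp2b13, Cyp2a4 and Sult3a1 were lower in treated males. The log2 fold change of Xist was -4.83 (SE 0.62, adjusted p 3.54e-06) at 300 mg/kg-d, but 4 of the 6 vehicle libraries carried 1.90 to 12.2 CPM of it and the other 2 at most 0.118. Sult3a1 was listed at 0 in all 6 libraries at 300 mg/kg-d.

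**Figure D2:**
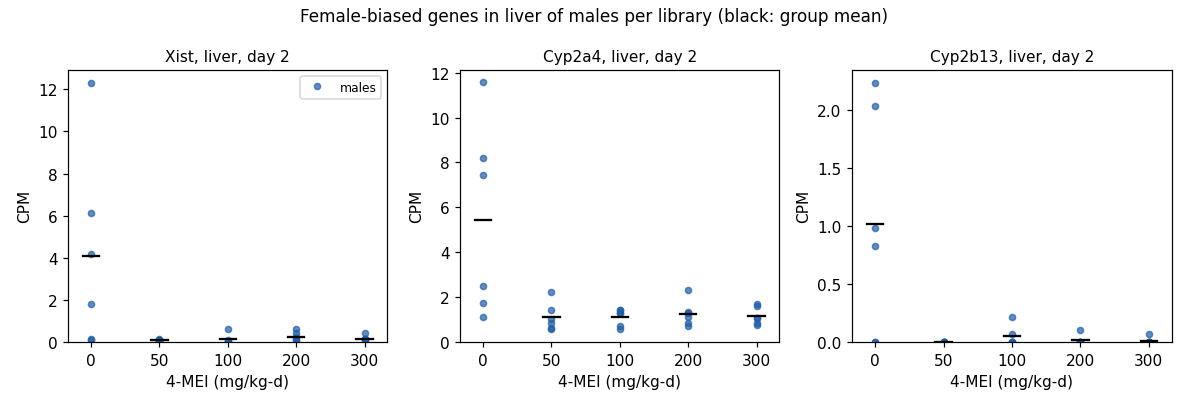
CPM (y axis) of Xist, Cyp2a4 and Cyp2b13 in liver of males at day 2 by dose (x axis, mg/kg-d), 1 point per library and a black line at the group mean. The vehicle mean of Xist was 4.10 CPM and that at 300 mg/kg-d 0.138 CPM.

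At 300 mg/kg-d 1091 genes were higher and 817 lower in males, and 1932 and 1855 in females. Of these, 871 were higher and 600 lower in both sexes, where independent lists would share 167 and 120. The lower doses did not follow in order in males, with 8, 594 and 2 genes at 50, 100 and 200 mg/kg-d. With only the groups compared edgeR called 0, 401 and 0 (1529 and 979 with an unadjusted p under 0.05 at 50 and 200 mg/kg-d), and DESeq2 on all groups called 45, 713 and 5. The 2 at 200 mg/kg-d were Xist and Cyp2a4, both lower. A direct test of 200 against 100 mg/kg-d in males called 64 genes higher and 55 lower. In females 0, 5 and 2119 genes passed at 50, 100 and 200 mg/kg-d, and 520 had an unadjusted p under 0.05 at 50 mg/kg-d, where DESeq2 called 0. The 5 were Camkmt, Gng7, Nsmce1 and Tomm40l, lower, and Samd1, higher. Only 1 gene passed there with place in the number block as a term and 1 without the low-count filter, and 18 with only the groups compared. At 50 mg/kg-d 1 gene passed with only the groups compared. Without replicate 64, in which the fasting-induced Igfbp1 reached 5584 CPM and at most 100.4 in the other 5, 546 genes passed at 200 mg/kg-d, and 3 passed with only the groups compared in the fit.

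Over the fixed lists, camera placed acute phase genes higher (median 0.41 in females, 13 of 19 genes past the threshold and 13 adjusted over the list alone, adjusted p 5.95e-07) and fatty acid synthesis genes lower (median -0.87 in females, 11 of 17, and 13 adjusted over the list alone). With an estimated correlation none of the lists passed in either sex, and the adjusted p of the acute phase list became 0.419 in females and 0.614 in males. At the preset correlation, sterol genes were lower in females (15 of 25, and 15 adjusted over the list alone) and PPAR-alpha targets higher (13 of 25, and 17 adjusted over the list alone). Interferon-stimulated genes were lower in females (8 of 19, and 10 adjusted over the list alone). In males 6 of the acute phase genes passed (6 adjusted over the list alone), 7 of fatty acid synthesis (11 adjusted over the list alone), 5 interferon-stimulated genes (7 adjusted over the list alone), 3 PPAR-alpha targets (4 adjusted over the list alone) and no sterol gene (0 adjusted over the list alone), with each list past the threshold of camera.

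In liver after 5 days of feeding, genes for drug-metabolising enzymes rose. Cyp2c29, Cyp2c50, Cyp2c54 and Cyp3a11 encode cytochrome P450 enzymes controlled by the nuclear receptors CAR and PXR. They rose in both sexes at 2500 ppm. In females, the sterol synthesis genes Msmo1 and Cyp51 rose as well.

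Cyp3a11 rose by 0.85 (SE 0.11, adjusted p 4.17e-06) in males and by 0.67 (SE 0.11, adjusted p 0.00109) in females. Cyp2c29 (chromosome 19, 39287044 to 39330713) rose by 0.76 and 0.94, Cyp2c50 by 0.52 and 0.40 and Cyp2c54 by 0.67 and 0.42. In males Cyp2b10 rose by 2.58 (SE 0.44, adjusted p 0.000873), in 6 of 6 libraries, from 5.89 CPM (SD 2.95, n = 6) to 34.9 (SD 23.1, n = 6). Cyp2c55 rose by 1.51, the transporter Slco1a4 by 0.92, and the aryl hydrocarbon receptor (AHR) targets Cyp1a2 and Nqo1 by 0.71 and 0.85. Cyp7b1, an oxysterol hydroxylase, fell by 0.88, Selenbp2 by 1.00 and the noncoding Malat1 by 1.13. In females the sterol genes Msmo1 and Cyp51 rose by 0.77 and 0.66, and the interferon regulator Irf7 fell by 0.57.

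In males 28 genes were higher and 24 lower at 2500 ppm, 13 passed at 1250 ppm and 5 at 300 ppm (BC024386, Ccnl2, Fam193b, Rpph1 and Tle2, all lower, and 0 without the low-count filter in edgeR, with 915 at an unadjusted p under 0.05, where DESeq2 called 4). In females 6 were higher and 1 lower at 2500 ppm, and 4 were higher at 1250 ppm: Cyp2c29, Cyp2c50, Cyp2c54 and Cyp2c55. With only the groups compared in the fit, 1, 3 and 29 genes passed in males at 300, 1250 and 2500 ppm. In females 0 then passed in edgeR at 1250 and 2500 ppm (347 and 635 with an unadjusted p under 0.05), where DESeq2, on all groups, called 5 and 24. No gene passed in edgeR in males at 150 ppm (440 with an unadjusted p under 0.05) or in females at 150 and 300 ppm (357 and 215), and DESeq2 called 0 in each. CAR and PXR targets were higher as a list in males (8 of 28, and 12 adjusted over the list alone, adjusted p 7.35e-20) and held with an estimated correlation (0.000116), as did AHR targets (2 of 6, and 2 adjusted over the list alone, 0.0134), while sterol genes (1 of 25, and 9 adjusted over the list alone) did not (0.0893). In females sterol genes (2 of 25, and 21 adjusted over the list alone) and CAR and PXR targets (2 of 28, and 5 adjusted over the list alone) held at 6.22e-05 and 0.00676. The lower interferon-stimulated list (1 of 19, and 7 adjusted over the list alone) held at 0.00191, and that of Kupffer cells, the macrophages of the liver (0 of 10, and 10 adjusted over the list alone), at 0.00635. The higher immediate early genes (0 of 11, and 0 adjusted over the list alone) held at 0.033 and bile acid genes (0 of 15, and 2 adjusted over the list alone) at 0.0499.

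**Figure D3:**
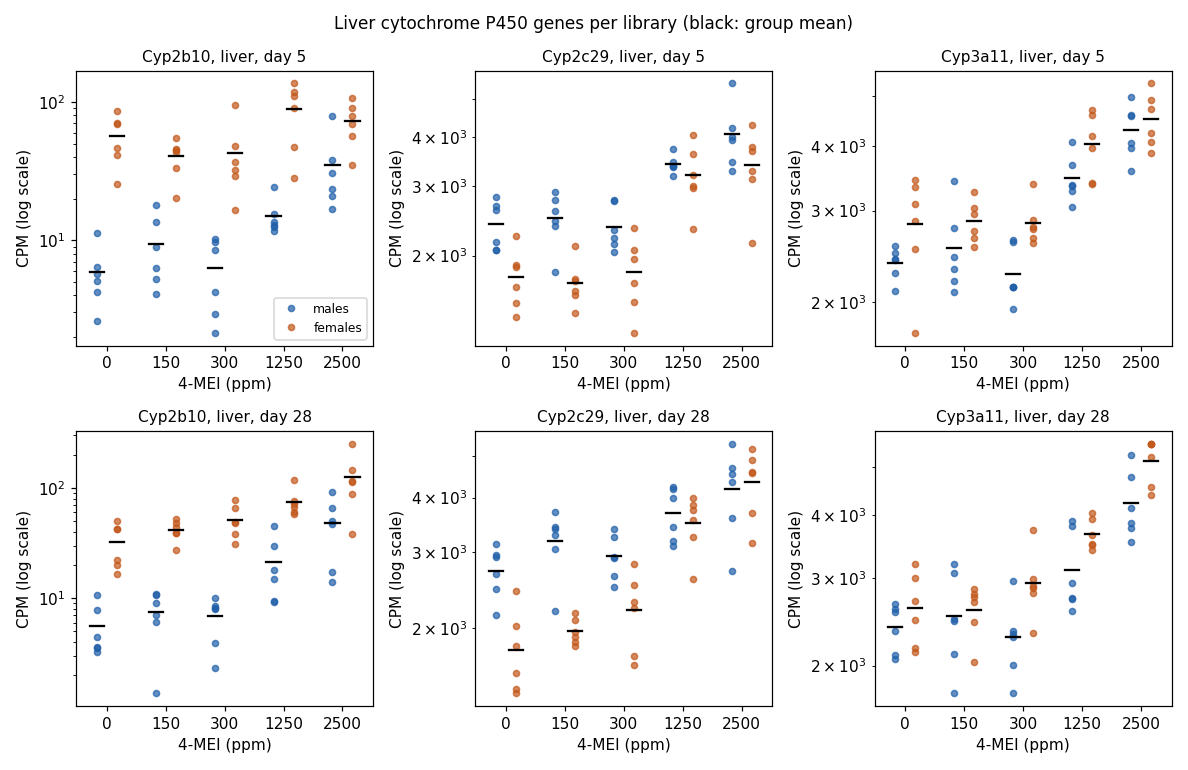
CPM on a log scale (y axis) of Cyp2b10, Cyp2c29 and Cyp3a11 in liver at day 5 (top) and day 28 (bottom) by dose (x axis, ppm), 1 point per library, males blue, females orange, black lines at group means. Cyp2b10 in males at day 28 had a mean of 5.57 CPM in vehicle and 47.6 CPM at 2500 ppm.

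In liver after 28 days, Cyp2b10, Cyp2c29, Cyp2c55 and Cyp3a11 rose in both sexes. In females, some liver genes with a female-biased pattern fell, among them Cyp3a16, Cyp3a41a and A1bg, whose level depends on the female rhythm of growth hormone. The interferon-stimulated genes Irf7, Usp18 and Bst2 fell in females.

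At 2500 ppm Cyp2b10 rose by 3.10 (SE 0.46, adjusted p 8.63e-05) in males and by 1.95 (SE 0.40, adjusted p 0.00423) in females. Cyp2c55 rose by 1.65 and 2.52, Cyp2c29 by 0.63 and 1.29 and Cyp3a11 by 0.82 and 0.98. In females Cyp3a16 (chromosome 5, 145436309 to 145469740) fell by 4.20 (SE 0.58, adjusted p 4.4e-06), from 50.2 CPM (SD 25.6, n = 6) to 2.70 (SD 1.61, n = 6). Cyp3a41a fell by 2.99, A1bg by 2.66 and Cyp3a44 by 1.16, each in 6 of 6 libraries. Serpina7, which encodes thyroxine-binding globulin, rose by 2.78 (SE 0.35, adjusted p 6.38e-07), the DNA repair gene Rad51b by 1.32, the activin antagonist Fst by 1.56 and the carboxylesterase Ces2a by 0.61. Irf7, Usp18 and Bst2, all interferon-stimulated, fell by 0.80, 0.74 and 0.50. In males Cyp2c50, Cyp2c54 and Zfand5 rose by 0.46, 0.58 and 0.45, and Fam53b and Slc39a4 fell by 0.61 and 0.45. Saa2 had a fold change of -2.33, from an uneven vehicle group of 29.6 CPM (SD 38.1, n = 6) to 5.97 (SD 2.64, n = 6), and the groups overlapped.

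In females 52 genes were higher and 98 lower at 2500 ppm (88 in total with only the groups compared in the fit), and 5 passed at 1250 ppm (Cyp2c29, Cyp2c55, Srxn1 and Ugt2b35 higher, Acsm2 lower, and 3 with only the groups compared and 13 with DESeq2). No gene passed in edgeR at 150 or 300 ppm (403 and 814 with an unadjusted p under 0.05), and DESeq2 called 0. In males 14, 2, 21 and 10 genes passed at 150, 300, 1250 and 2500 ppm. DESeq2 called 100, 7, 202 and 23, and edgeR with only the groups compared in the fit called 0, 0, 0 and 2 (1263, 439, 1170 and 623 with an unadjusted p under 0.05). Those at 300 ppm were Saa1 and Saa2, lower. The vehicle group was uneven in both (Saa1 117.1 CPM, SD 123.6, n = 6) and overlapped the dose group. The female-biased list was lower in females (5 of 16, and 10 adjusted over the list alone) and held with an estimated correlation (0.00639). CAR and PXR targets held in males (4 of 28, and 9 adjusted over the list alone, 0.0493). In females they did not (5 higher and 1 lower, 11 and 1 adjusted over the list alone, 0.133), nor did the interferon-stimulated list (3 of 19, and 7 adjusted over the list alone, 0.108).

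In lung after 2 days of gavage, Prf1 and Pdpn fell in both sexes and Aqp5 fell in females at 300 mg/kg-d. Prf1 encodes perforin, the pore-forming protein of killer cells. Pdpn and Aqp5 mark the thin cells that line the air sacs. The aldehyde dehydrogenase gene Aldh3a1, an AHR target, rose.

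At 300 mg/kg-d Aldh3a1 rose by 1.01 (SE 0.19, adjusted p 0.00591) in males and by 1.32 (SE 0.19, adjusted p 9.18e-06) in females. Ly6c1, an endothelial surface gene, rose by 0.68 and 0.85, the peroxisomal thiolase Acaa1b by 0.91 and 0.85, Rasl11a by 0.87 and 0.93, Fam189a2 by 0.41 in each sex and Rbm15 by 0.41 and 0.34. Prf1 fell by 1.42 and 1.28, Gsg1l by 1.75 and 2.36, the receptor Epha1 by 0.59 and 0.75, the adenosine-producing Nt5e by 0.60 and 0.62, Olfml3 by 0.48 and 0.90, Prkag3 by 0.76 and 0.72, and the type 1 cell genes Pdpn by 0.43 and 0.69 and Emp2 by 0.28 and 0.25. In females Gzma, Nkg7, Klrd1 and Cd3g fell by 1.42, 1.39, 0.97 and 0.84, Aqp5 and Igfbp2 by 0.47 and 0.60, and the clock repressor Nr1d1 by 1.84. The clock genes Arntl and Dbp followed the place of the title's number in its block in these lungs. Each dose held its own block, and the order of the blocks was not tested. Time of collection therefore cannot be separated from dose for Nr1d1. Acot1, Acot2 and Angptl4, of fat use, rose by 1.15, 0.42 and 1.80. Ctla2a, Foxs1 and Gsta2 rose by 0.80, 1.12 and 0.81 in males, and Gpm6a and Slc36a2 fell by 0.59 and 0.51. Prg4, Alox15 and Tnnt3 were higher in females by 5.39, 4.80 and 2.35, with replicate 75 far above the others. The next libraries held 21.1, 12.9 and 2.08 CPM, against vehicle means of 0.86, 0.95 and 1.33, and for Prg4 the groups did not overlap. A fit without replicate 75 was not run. The calls of Alb and Ahsg, with fold changes of -4.75 and -2.95, went with vehicle replicate 12, which held 257 CPM of Alb where the next library held 4.60.

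In males 16 genes were higher and 16 lower, and 172 passed without replicate 66. In a fit of only the groups compared, 0 passed in edgeR in males (718 with an unadjusted p under 0.05), and DESeq2 on all groups called 0.991% of the genes tested. In females 555 were higher and 775 lower, and 998 passed without replicate 78. At 200 mg/kg-d 825 genes passed in females, and 51 higher and 87 lower without replicate 64. A fit of only the groups compared called 10 at 200 and 2729 at 300 mg/kg-d. Bcl6 in males and Mpv17l in females, both lower, passed at 100 mg/kg-d, where 17 genes in males and 31 higher and 75 lower in females passed with only the groups compared. In fits of all groups no gene passed in edgeR at 50 mg/kg-d (421 and 441 with an unadjusted p under 0.05 in males and females), where DESeq2 called 1 and 2, or in males at 200 mg/kg-d (1323), where DESeq2 called 23. Other edgeR fits did call genes in these groups, with 12 lower in females at 50 mg/kg-d without the low-count filter and 60 higher and 56 lower in males at 200 mg/kg-d with only the groups compared. The T and NK cell list was lower in females (5 of 9, and 7 adjusted over the list alone), as was the type 1 list (4 of 10, and 4 adjusted over the list alone), and PPAR-alpha targets were higher (6 of 21, with 11 higher and 1 lower adjusted over the list alone). None held with an estimated correlation (0.187, 0.109 and 0.518). In males 0 of 9, 2 of 10 and 1 of 21 genes of these lists passed (1, 2 and 6 adjusted over the list alone), and none of these lists held (0.696, 0.185 and 0.696).

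In lung after 5 days of feeding, few genes passed. Nqo1, a quinone reductase under NRF2 and AHR control, and the AHR target Cyp1b1 rose in females. Ces1g, a carboxylesterase, rose with them.

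At 2500 ppm in females Nqo1 (chromosome 8, 107388225 to 107403205) rose by 0.97 (SE 0.15, adjusted p 0.00031), from 9.80 CPM (SD 1.72, n = 6) to 19.2 (SD 5.95, n = 5), in 5 of 5 libraries. Ces1g rose by 1.25, Cyp1b1 by 0.88, Foxn4, of multiciliated cell formation, by 1.44 and Klk1 by 3.07, the last with Lung_159 at 16.1 CPM and the next at 0.669. AHR targets were higher as a list (2 of 7, and 5 adjusted over the list alone) and held with an estimated correlation (0.0023). In females 0, 2 and 7 genes passed at 150, 300 and 1250 ppm and 5 at 2500 ppm. In a fit of only the groups compared edgeR called 0, 198, 0 and 2 (445 and 776 with an unadjusted p under 0.05 at 150 and 1250 ppm), where DESeq2 on all groups called 0, 36, 35 and 10. The 2 were Nfkbib and Myh4, both lower. Vehicle replicate 090 held 105.6 CPM of Myh4, a skeletal muscle myosin, and the next library 0.579. In fits of all groups 6 genes passed in males at 1250 ppm and none in edgeR at 150, 300 and 2500 ppm (1954, 1336 and 1328 with an unadjusted p under 0.05), where DESeq2 called 13, 1 and 3. Without the low-count filter edgeR called 16 at 300 ppm and 0 at 1250 ppm (1666 with an unadjusted p under 0.05, and 59 called by DESeq2). In females at 150 ppm 338 genes had an unadjusted p under 0.05 and DESeq2 called 0.

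**Figure D4:**
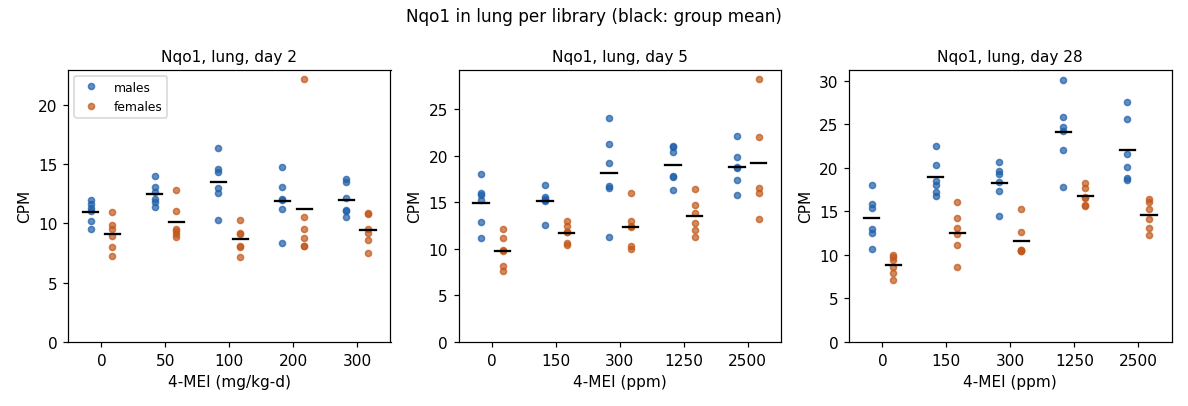
CPM (y axis, from 0) of Nqo1 in lung at days 2, 5 and 28 by dose (x axis, mg/kg-d or ppm), 1 point per library, males blue, females orange, black lines at group means. At day 28 the means in females were 8.82 CPM in vehicle and 14.5 CPM at 2500 ppm.

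In lung after 28 days, Nqo1 rose in both sexes. The cystine transporter gene Slc7a11, another NRF2 target, rose in females. Lower calls of skeletal muscle genes in treated females went with 1 vehicle library, replicate 176.

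Nqo1 rose at 2500 ppm by 0.63 (SE 0.12, adjusted p 0.0261) in males and by 0.72 (SE 0.13, adjusted p 0.00765) in females, and at 1250 ppm by 0.76 in males. Slc7a11 rose by 0.47 in females. Counts at the locus of Mir703, which in mRNA libraries do not measure the microRNA itself, rose by 1.02 in males at 2500 ppm, and Gpihbp1, Il1f9, Psmb7 and Snrpb by 0.40, 1.14, 0.42 and 0.34 at 1250 ppm. Ucp1 and Krt15 were higher in females by 7.17 and 5.62, and Ucp1 lay above the vehicle mean in 2 of 6 libraries. Both went with replicate 238, at 110 CPM of Ucp1 and 83.9 of Krt15, where the next libraries held 0.252 and 1.01. Cxcl13 had a fold change of -3.50, with 162 CPM in vehicle replicate 171 and 4.13 in the next. Actn3, Atp2a1, Mylpf, Tnni2 and Tnnt3, which build fast skeletal muscle, had fold changes of -2.73, -2.79, -3.31, -2.88 and -4.14 at 150 ppm. Vehicle replicate 176 held 79.5 CPM of Mylpf and the next library 1.65. The counts were 5, 24, 13 and 19 in females over the doses, and 0, 8, 7 and 4 without replicate 176. With only the groups compared in the fit edgeR called 0, 0, 1 and 0 in females (650, 1419, 926 and 1540 with an unadjusted p under 0.05), and DESeq2 on all groups called 7, 47, 15 and 65. In males 0, 0, 5 and 2 genes passed (1077 and 1039 with an unadjusted p under 0.05 at the lower doses in edgeR, and 0 and 0 called by DESeq2). A fit of only the groups compared called 0, 0, 0 and 13 in edgeR (1244, 976 and 1946 with an unadjusted p under 0.05 at the lower 3 doses), and DESeq2 on all groups called 48 at 1250 ppm. At 300 ppm 11 genes passed with place as a term and 8 with the length trend removed. NRF2 targets were higher as a list in males (1 of 25, and 5 adjusted over the list alone) and females (2 of 25, and 5 adjusted over the list alone), and did not hold with an estimated correlation (0.168 and 0.107). AHR targets held in females (1 of 7, and 3 adjusted over the list alone, 0.0275) and not in males (1 of 7, and 1 adjusted over the list alone, 0.168).

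The sexes were compared by testing the difference of their effects at the highest dose. At day 2 in liver only Xist passed in edgeR with all groups, where DESeq2 called 5 genes, and edgeR with only the groups compared called 0 (733 with an unadjusted p under 0.05). At day 28 in liver 5 genes passed (11 with DESeq2 and 9 with only the groups compared): the female-biased Cyp3a44 and the sulfotransferase Sult5a1 had lower effects in females, and Olfm2, Islr and Htra1, of the extracellular matrix, higher ones. The fold change of Cyp3a44 was 1.14 in males and -1.16 in females, a difference of 2.29 (SE 0.45, adjusted p 0.0232), and that of Sult5a1 was -0.12 and -1.71. The next genes at day 2 in liver were Sult3a1, Ppp2r5e and Cyp2a4 (adjusted p 0.0928, 0.0928 and 0.124). No gene passed in edgeR in lung at days 2, 5 and 28 or in liver at day 5 (1964, 549, 1302 and 521 with an unadjusted p under 0.05), and DESeq2 called 0, 0, 0 and 2. The smallest adjusted p was 0.338 in lung at day 2 (Tmem17, Pim1, Wnt4 and Tubb2a), 1 at day 5 (Tmc7, Tnfrsf19, Gata4 and Tmem221) and 0.233 at day 28 (Esd, Tnni2, Pomp and Ctla2a), and in liver at day 5 0.159 for Scp2, before H3f3a, Srsf10 and Jchain.

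Liver and lung were compared in the same way. At day 2 in females 1971 genes differed (1392 with the higher effect in liver and 579 with the lower, and 1115 and 749 with RLE size factors). The adhesion gene Vcam1 led them, with 0.97 in liver and -0.24 in lung (adjusted p 1.74e-06), before Arhgap5, Itpr1 and Tnpo1. In males Gsta2, Col20a1, Rnf144b and Nt5e differed, and the fold change of Nt5e was 0.79 in liver and -0.58 in lung (adjusted p 0.0459). At day 5 Cyp2b10 differed in males, with 2.59 in liver and -0.08 in lung (adjusted p 0.015), with Anpep, Selenbp2, Gstt3 and Npc1, and Ces1g differed in females, with 0.02 in liver and 1.25 in lung (adjusted p 0.0248). These fits did not pair libraries by title number. Fits with the numbers as a block held only the numbers found in both tissues. In them the calls in males at day 5 and that of Ces1g were lost, and fewer genes differed in females at day 2. Of the calls in females at day 28, most of those with the higher effect in liver were lost as well. At day 28 Sult5a1, Id1, Htra1 and Frrs1 led 11 genes in females, and no gene passed in edgeR in males (1078 with an unadjusted p under 0.05, and 18 called by DESeq2), where Cyp2b10 came first at an adjusted p of 0.074, before Gss, Alox12 and Dpep1 at 0.327. The next genes in females at day 5 were Hsd17b7, Mycl and Ces1f (0.343).

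Day 28 and day 5 were compared at 2500 ppm. In liver of females the fold change of Rad51b was 1.32 at day 28 and -0.78 at day 5 (difference 2.10, SE 0.27, adjusted p 0.000345), and the matrix gene Fbln5, the hormone receptor Pth1r and the urate pathway gene Urad differed as well. No gene passed in edgeR in liver of males or in lung of males and females (513, 1352 and 1029 with an unadjusted p under 0.05), where DESeq2 called 0, 15 and 4. The smallest adjusted p was 0.92 in liver of males (Pnrc1, Malat1, Cox20 and Rpph1), 0.116 in lung of males (Uqcrb, Gstm2 and Mrpl42, before Nabp2) and 0.166 in lung of females (4933434E20Rik, before Ccno, Rpl22l1 and Stard3nl).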

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

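The tests of female RNA, transcript length, place in the number block and skeletal muscle were chosen after the results were seen. Counts over other splits of the libraries were planned.

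Single libraries stood far from the other libraries of their group in 45 of 406 checks of the named genes. Chance alone gives about 1 in 20 for values with a normal spread in genes not chosen by their fold changes. The named genes were partly chosen so. A vehicle group could also enter the checks more than once for a gene, with its outlying library counted once. The rates are therefore no like comparison. In liver of males at day 2 with 300 mg/kg-d, replicate 67 stood above the others in Saa1 (1903 CPM), Saa2 (1172 CPM), Lcn2 (38.96 CPM), Hp (5461 CPM) and Xist (0.3996 CPM), replicate 66 in Acot1 (137.9 CPM) and replicate 68 in Cyp2b13 (0.0652 CPM, the others at 0). Vehicle replicate 06 stood above in Hp (3078 CPM), and replicate 50 at 200 mg/kg-d in Cyp2a4 (2.31 CPM). In liver of females at day 2, vehicle replicate 10 stood below in Camkmt (0.647 CPM) and vehicle replicate 09 below in Hp (1375 CPM) and above in Cyp4a31 (39.7 CPM). Vehicle replicate 11 stood above in Mt2 (99.8 CPM) and Saa1 (38.02 CPM), and at 300 mg/kg-d replicate 75 in Mt2 (521 CPM) and Xaf1 (5.73 CPM) and replicate 77 in Acot1 (201 CPM).

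In lung of males at day 2, replicate 66 at 300 mg/kg-d stood above in Acaa1b (67.7 CPM), Ctla2a (704 CPM), Gsta2 (9.69 CPM) and Ly6c1 (714 CPM) and below in Nt5e (64.6 CPM), and vehicle replicate 08 stood below in Bcl6 (60.1 CPM). In lung of females at day 2, vehicle replicate 12 stood above in the liver genes Alb (257 CPM) and Ahsg (38.4 CPM). At 300 mg/kg-d replicate 75 stood above in Alox15 (134.003 CPM), Prg4 (178 CPM), Tnnt3 (34.3 CPM) and Cd3g (6.54 CPM), and replicate 78 below in Aqp5 (292 CPM). At day 5, Day5_LIVER_146 stood above in Cyp2b10 (79.4 CPM) in liver of males at 2500 ppm, vehicle replicate 090 in Myh4 (105.6 CPM) and Lung_159 in Klk1 (16.1 CPM) in lung of females. At day 28, replicate 240 stood above in Cyp3a44 (259 CPM) in liver of females at 2500 ppm. In lung of females, vehicle replicate 176 stood above in Actn3 (73.6 CPM), Atp2a1 (262 CPM), Mylpf (79.5 CPM), Tnni2 (70.1 CPM) and Tnnt3 (170 CPM), and vehicle replicate 171 in Cxcl13 (162 CPM) and Ucp1 (0.521 CPM). Replicate 238 at 2500 ppm stood above in Krt15 (83.9 CPM), Ucp1 (110 CPM), Tnni2 (2.68 CPM) and Tnnt3 (8.18 CPM).

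The effect of the highest dose differed between groups by a test of the difference for 1 gene between the sexes in liver at day 2 (Xist) and for 5 at day 28, of which Cyp3a44 and Sult5a1 were lower in females. Between liver and lung it differed for 4 genes in males and 1971 in females at day 2, 5 in males and 1 in females at day 5, and 11 in females at day 28. Between day 28 and day 5 it differed for 4 genes in liver of females, with Rad51b first. Over 30 splits, the counts of 4, 1971, 5 and 11 genes between tissues lay above all others (highest other 0, 2, 3 and 0), as did the 4 between days (0). So few splits cannot exclude chance for a single count. The tissue splits were fitted without the title numbers as a block. With that block the 5 genes in males at day 5 lost their calls, and fewer than 1971 differed in females at day 2. In females at day 28 most of the calls with the higher effect in liver were lost with it. The real count did not lead for Ces1g in females at day 5, where another split gave 21 and the block ended the call. Nor did it lead for the sex differences, where the highest other split gave 1187 genes in liver at day 2 and 7 at day 28.

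Xist and the female-biased Cyp2a4, Cyp2b13 and Sult3a1 were lower in liver of males at day 2 at 200 or 300 mg/kg-d. Over 17 female-biased genes, these 3 included, the median was -1.84, -1.75, -1.02 and -1.39 at 50, 100, 200 and 300 mg/kg-d, with 17, 16, 15 and 16 below 0. The 17 held at least 20 CPM in female vehicle and at least 20 times the mean of treated males. This choice favours genes low in treated males, so the tally is partly built in. With Xist counted, 3, 5, 2 and 5 passed as lower. A candidate explanation is a small share of female liver RNA in vehicle libraries: over the 4 with Xist above 1 CPM, the excess of the 17 genes was 1.08 times that expected from Xist (median). The 4 ratios spread widely, from -0.0963 in replicate 05 through 0.753 in 06 and 1.41 in 07 to 2.32 in 08. A lower level of these genes after 4-MEI stays open. In the other vehicle libraries, replicates 01 and 03, the genes had a median log2 ratio of -0.080 to treated males (quartiles -0.30 and 0.32).

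Genes higher in liver at day 2 with 300 mg/kg-d had longer transcripts (median 2372.5 bases in males and 2132 in females) than genes lower (900 and 965). After removal of a transcript length trend 1480 genes in males and 3390 in females still passed, so a trend of the fitted form did not account for all calls. The highest other splits, 297 and 1658, were fitted with the trend left in, and none was fitted without it, so they are no like comparison. With the place in the block of title numbers as a term 2179 and 3893 passed. Each group spans places of its own block, and the splits were fitted without the term, so these counts cannot decide on place. Library totals were also higher at 300 mg/kg-d (14905474 to 17758970 counts in males) than in vehicle (8457034 to 12857743). An effect of 4-MEI and a shared preparation of the libraries of a group, for which the labels give no batch, stay open.

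Skeletal muscle genes such as Mylpf, Tnni2 and Tnnt3 were lower in lung of females at all 4 doses at day 28. A candidate explanation is skeletal muscle in vehicle replicate 176, in which the list lay 6.70 log2 above the other 5 vehicle libraries (median). Without it, 0 of the 10 list genes tested passed in edgeR at any dose, where 5, 6, 6 and 6 had passed. A fall of the size called is argued against, since the list medians over the doses were then 0.16 to 0.38, and -2.64 to -2.27 before. No standard error was computed for these medians. The next vehicle library held only 1.65 CPM of Mylpf, so a small change after 4-MEI stays open.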

How the results depend on the processing

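The terms for place and transcript length and the fits without replicates 64, 66, 78 and 176 were tests chosen after seeing the data. With 8457034 to 20405658 counts per liver library at day 2, for example, the test on simulated data recovered 67.2% of 1.5-fold changes in males, so small changes of single genes could be missed. Of 203 calls of named genes, none changed direction with RLE size factors, DESeq2 or only the groups compared, the alternatives run on single genes. All 203 kept their side of the threshold with RLE size factors and 187 with DESeq2, where 16 lost it. With only the groups compared 110 kept it, 84 lost it and 9 gave no value, in fits with fewer samples. Counts of genes moved by over 1.5 times in 40 of 64 results with DESeq2, 37 of 54 with only the groups compared, 13 of 64 without the filter, 13 of 54 with place, 10 of 54 with length and 1 of 64 with RLE size factors. The cause was not tested unless stated. Percentages are of the genes tested in that fit, and counts were compared.

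With DESeq2 the number of genes became 45 at 50 mg/kg-d (0.357%, from 8) and 5 at 200 mg/kg-d (0.0397%, from 2) in liver of males at day 2, and 18 at 100 mg/kg-d (0.143%, from 5) in liver of females at day 2. They numbered 5 (0.0397%, from 1) for the difference between the sexes in liver at day 2, and 1 at 50 mg/kg-d (0.00657%, from 0), 2 at 100 mg/kg-d (0.0131%, from 1), 23 at 200 mg/kg-d (0.151%, from 0) and 0.991% at 300 mg/kg-d (from 32 genes) in lung of males at day 2. The number was 2 at 50 mg/kg-d (0.0131%, from 0) and 10 at 100 mg/kg-d (0.0657%, from 1) in lung of females at day 2, and 21 at 1250 ppm (0.164%, from 13) and 94 at 2500 ppm (0.732%, from 52) in liver of males at day 5. It was 24 at 2500 ppm (0.187%, from 7) in liver of females at day 5, and 2 (0.0156%, from 0) for the difference between the sexes in liver at day 5. They numbered 13 at 150 ppm (0.0831%, from 0), 1 at 300 ppm (0.00639%, from 0), 59 at 1250 ppm (0.377%, from 6) and 3 at 2500 ppm (0.0192%, from 0) in lung of males at day 5, and 36 at 300 ppm (0.230%, from 2), 35 at 1250 ppm (0.224%, from 7) and 10 at 2500 ppm (0.0639%, from 5) in lung of females at day 5. The number was 100 at 150 ppm (0.775%, from 14), 7 at 300 ppm (0.0542%, from 2), 202 at 1250 ppm (1.57%, from 21) and 23 at 2500 ppm (0.178%, from 10) in liver of males at day 28, and 13 at 1250 ppm (0.101%, from 5) and 239 at 2500 ppm (1.85%, from 150) in liver of females at day 28. It was 11 (0.0852%, from 5) for the difference between the sexes in liver at day 28, and 48 at 1250 ppm (0.307%, from 5) and 11 at 2500 ppm (0.0704%, from 2) in lung of males at day 28. They numbered 47 at 300 ppm (0.301%, from 24) and 65 at 2500 ppm (0.416%, from 19) in lung of females at day 28, and 82 (0.542%, from 4) for the difference between tissues in males at day 2. The number was 63 (0.409%, from 5) for the difference between tissues in males at day 5, and 16 (0.103%, from 1) for the difference between tissues in females at day 5. It was 18 (0.117%, from 0) for the difference between tissues in males at day 28, and 0.661% (from 11 genes) for the difference between tissues in females at day 28. They numbered 38 (0.2996%, from 4) for the difference between days in liver of females, and 15 (0.0983%, from 0) for the difference between days in lung of males. The number was 4 (0.0262%, from 0) for the difference between days in lung of females.

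With only the groups compared in the fit the number of genes became 0 at 50 mg/kg-d (from 8) and 0 at 200 mg/kg-d (from 2) in liver of males at day 2, and 1 at 50 mg/kg-d (0.00822%, from 0), 18 at 100 mg/kg-d (0.147%, from 5) and 3 at 200 mg/kg-d (0.0251%, from 2119) in liver of females at day 2. They numbered 0 (from 1) for the difference between the sexes in liver at day 2, and 17 at 100 mg/kg-d (0.116%, from 1), 0.794% at 200 mg/kg-d (from 0 genes) and 0 at 300 mg/kg-d (from 32) in lung of males at day 2. The number was 2 at 50 mg/kg-d (0.0136%, from 0), 0.720% at 100 mg/kg-d (from 1 genes), 10 at 200 mg/kg-d (0.0680%, from 825) and 2729 at 300 mg/kg-d (18.5%, from 1330) in lung of females at day 2, and 1 at 300 ppm (0.00840%, from 5), 3 at 1250 ppm (0.0251%, from 13) and 29 at 2500 ppm (0.243%, from 52) in liver of males at day 5. It was 0 at 1250 ppm (from 4) and 0 at 2500 ppm (from 7) in liver of females at day 5, and 1 at 300 ppm (0.00671%, from 0) and 2 at 1250 ppm (0.0134%, from 6) in lung of males at day 5. They numbered 198 at 300 ppm (1.32%, from 2), 0 at 1250 ppm (from 7) and 2 at 2500 ppm (0.0133%, from 5) in lung of females at day 5, and 0 at 150 ppm (from 14), 0 at 300 ppm (from 2), 0 at 1250 ppm (from 21) and 2 at 2500 ppm (0.0167%, from 10) in liver of males at day 28. The number was 3 at 1250 ppm (0.0244%, from 5) and 88 at 2500 ppm (0.712%, from 150) in liver of females at day 28, and 9 (0.0719%, from 5) for the difference between the sexes in liver at day 28. It was 0 at 1250 ppm (from 5) and 13 at 2500 ppm (0.0866%, from 2) in lung of males at day 28, and 0 at 150 ppm (from 5), 0 at 300 ppm (from 24), 1 at 1250 ppm (0.00670%, from 13) and 0 at 2500 ppm (from 19) in lung of females at day 28. They numbered 1 (0.00654%, from 0) for the difference between the sexes in lung at day 28.

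Without the low-count filter the number of genes became 5 at 50 mg/kg-d (0.0268%, from 8) in liver of males at day 2, and 1 at 100 mg/kg-d (0.00536%, from 5) in liver of females at day 2. They numbered 12 at 50 mg/kg-d (0.0583%, from 0) and 29 at 100 mg/kg-d (0.141%, from 1) in lung of females at day 2, and 0 at 300 ppm (from 5) in liver of males at day 5. The number was 16 at 300 ppm (0.0746%, from 0) and 0 at 1250 ppm (from 6) in lung of males at day 5, and 3 at 2500 ppm (0.0140%, from 5) in lung of females at day 5. It was 8 at 1250 ppm (0.0404%, from 21) in liver of males at day 28, and 95 at 2500 ppm (0.480%, from 150) in liver of females at day 28. They numbered 14 at 150 ppm (0.0657%, from 5), 21 at 1250 ppm (0.0985%, from 13) and 29 at 2500 ppm (0.136%, from 19) in lung of females at day 28.

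With RLE size factors the number of genes became 7 (0.0462%, from 4) for the difference between tissues in males at day 2.

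With the place in the number block as a term the number of genes became 1 at 200 mg/kg-d (0.00792%, from 2) in liver of males at day 2, and 1 at 100 mg/kg-d (0.00792%, from 5) in liver of females at day 2. They numbered 77 at 300 mg/kg-d (0.505%, from 32) in lung of males at day 2, and 1 at 50 mg/kg-d (0.00656%, from 0) and 4 at 100 mg/kg-d (0.0262%, from 1) in lung of females at day 2. The number was 21 at 2500 ppm (0.164%, from 7) in liver of females at day 5, and 20 at 1250 ppm (0.128%, from 6) in lung of males at day 5. It was 86 at 150 ppm (0.666%, from 14) and 0.806% at 1250 ppm (from 21 genes) in liver of males at day 28, and 11 at 300 ppm (0.0703%, from 0) in lung of males at day 28. They numbered 2 at 150 ppm (0.0128%, from 5), 4 at 300 ppm (0.0256%, from 24) and 4 at 1250 ppm (0.0256%, from 13) in lung of females at day 28.

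With the length trend removed the number of genes became 1 at 50 mg/kg-d (0.00656%, from 0), 2 at 100 mg/kg-d (0.0131%, from 1) and 3 at 200 mg/kg-d (0.0197%, from 0) in lung of males at day 2, and 3 at 100 mg/kg-d (0.0197%, from 1) in lung of females at day 2. They numbered 11 at 1250 ppm (0.0702%, from 6) and 1 at 2500 ppm (0.00638%, from 0) in lung of males at day 5, and 8 at 300 ppm (0.0511%, from 0), 8 at 1250 ppm (0.0511%, from 5) and 8 at 2500 ppm (0.0511%, from 2) in lung of males at day 28. The number was 41 at 300 ppm (0.262%, from 24) in lung of females at day 28.

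Without replicate 64, 546 (4.31%) genes passed in liver (from 2119) and 0.903% in lung (from 825 genes) of females at day 2 with 200 mg/kg-d. Without replicate 66, 172 (1.13%) passed in lung of males at 300 mg/kg-d (from 32). Without replicate 78, 998 (6.53%) passed in lung of females at 300 mg/kg-d (from 1330). Without vehicle replicate 176, the counts in lung of females at day 28 were 0, 8 (0.0508%), 7 (0.0445%) and 4 (0.0254%) over the doses (from 5, 24, 13 and 19). Leaving out each replicate in turn, lung of females at day 5 with 2500 ppm gave 1 to 7 genes (0.00638% to 0.0444%, from 5), with 1 without vehicle replicate 089 and 3 without 090, 096 or Lung_155.

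Liver and lung titles share numbers, and the labels do not say that a number marks 1 animal. With the replicate block of these numbers, the genes that differ between tissues became 737 (4.82%) in place of 1971 in females at day 2 and 0 (from 5) in males at day 5, and no other count moved by over 1.5 times. In females at day 5 the 1 gene became 1 higher and 0 lower in liver (from 0 and 1), so the call of Ces1g was lost, and at day 28 the calls became 1 and 11 (from 5 and 6). Same-numbered deviations correlated by over 0.1 in 6 of 11 pairs in males and 6 of 8 in females at day 2, 8 of 10 and 1 of 7 at day 5 and 6 of 10 and 6 of 8 at day 28. Liver correlated best with its own number in 7, 8, 5, 1, 6 and 7 of these pairs. This is a hint from the data that same-numbered libraries belong together, most at day 2 in females (8 of 8), but not every pair passed 0.1. A weak correlation does not show that libraries are unpaired. The main fits used no pairing, as the labels state none, so the tissue differences that the block ended are uncertain. The block fits held only the numbers found in both tissues. In data simulated for females at day 5 they recovered 53.7% of genes changed 2-fold, and the fits without the block 74.6%. A lost call can therefore also come from a less sensitive fit. In females at day 5 the median correlation was -0.104 for the same number and 0.027 for other numbers.

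With an estimated correlation, the number of lists past the threshold in females and males became 0 and 0 in liver at day 2 (from 7 and 9), 6 and 2 at day 5 (from 12 and 9) and 1 and 1 at day 28 (from 13 and 6). In lung it became 0 and 0 at day 2 (from 11 and 8), 1 and 0 at day 5 (from 12 and 11) and 1 and 0 at day 28 (from 16 and 7). With fry it became 11 in liver of females at day 2, 6 and 3 in females and males at day 5 and 2 in males at day 28. In lung fry gave 3 and 2 at day 2, 1 and 0 at day 5 and 3 and 0 at day 28. With a prior count of 0.5 all 12 stayed within 1.5 times.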

Other observations

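The relation of clock genes to the numbers in the titles was tested after it was seen, and the other splits were planned.

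Arntl, the core activator of the circadian clock, followed the place of the title's number in its block of 8. With group means removed, Spearman's rho was 0.69 in liver and 0.61 in lung at day 2 (60 libraries each), -0.92 and -0.97 at day 5 (60 and 59) and -0.89 and -0.89 at day 28 (60 each). Pearson's r was 0.70, 0.63, -0.91, -0.96, -0.89 and -0.91, and 0.67, 0.61, -0.90, -0.96, -0.88 and -0.90 without the 2 libraries farthest in place. Each permutation p (100000 permutations within groups, two-sided) was 1e-05, the smallest they can give, and 1e-05 adjusted over 12 relations. Dbp, a clock output gene, ran the opposite way in all 6 tables. A candidate explanation is that the animals of each block were taken in the order of their numbers over hours. The order of the blocks themselves was not tested, as group means were removed. Why the sign at day 2 was opposite to that at days 5 and 28 was not tested either. With place as a term, 950 genes in liver and 727 in lung at day 2, 4063 and 2351 at day 5 and 4661 and 2552 at day 28 passed for place itself.

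Over 30 splits of the same libraries, the real one included, the real count lay above all other splits for 13 of 48 counts of genes against vehicle. In liver at day 2 these were 8 genes in males at 50 mg/kg-d (highest other 7), 594 at 100 (9) and 1908 at 300 (297), and 5 in females at 100 mg/kg-d (1), 2119 at 200 (995) and 3787 at 300 (1658). In lung at day 2 they were 1 in males at 100 mg/kg-d (0) and 825 and 1330 in females at 200 and 300 mg/kg-d (0.925% of the genes tested, and 775 genes). In feed they were 7 in liver and 5 in lung of females at 2500 ppm at day 5 (5 and 4), and 5 and 150 in liver of females at 1250 and 2500 ppm at day 28 (0 and 40). Leading the splits was not adjusted over the 48 counts. With 30 splits chance cannot be excluded for a single count, least of all at margins such as 8 against 7. Some of these counts also rest on single libraries. Without replicate 64 the 2119 and 825 genes became 546 and 0.903% of the genes tested, below the highest other splits of all libraries. No splits were fitted without that replicate, so this is no like comparison. Without vehicle replicate 089 the 5 genes in lung at day 5 became 1. In 15 results the real count was 0 and other splits gave up to 2711. In 20 the real count was above 0 and was reached or passed, with 2 to 30 of the 30 splits as large (4 for lung of males at day 2 with 300 mg/kg-d, 7 and 9 for lung of males and females at day 28 with 2500 ppm, 10 for liver of males at day 28 with 300 ppm). Splits with many times the real count point to a structure of the samples, whose source was not tested. The splits were fitted without place as a term and may differ in it, and how the counts would rank with the term was not tested. Nqo1 in lung of both sexes at day 28, Cyp2b10 in liver of males at days 5 and 28 and the calls in lung of males at day 2 with 300 mg/kg-d, such as Aldh3a1, belong to counts that other splits reached or passed.

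The number of lists past the threshold lay above all other splits in liver (13, highest other 10) and lung (16, highest other 15) of females at day 28. It did not in the other 10 results: splits as large numbered 9 in males and 15 in females in liver at day 2, 3 and 9 in lung at day 2, 3 and 2 in liver at day 5, 3 and 5 in lung at day 5, and 8 in liver and 17 in lung of males at day 28. For the 64 genes higher and 55 lower between 200 and 100 mg/kg-d in liver of males at day 2, the highest other split gave 10.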
